A study of Mus musculus with 6 samples.

How the data were processed

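RNA was sequenced from 6 murine brainstem gliomas, of which 3 carried the H3.3K27M mutation and 3 did not. Per the labels' protocols, each tumour was snap frozen, total RNA was extracted, and Illumina libraries were made and sequenced by a service provider. The series' design text calls the 3 tumours of each group independent, so each tumour was treated as 1 replicate. Groups were taken from the sample titles, and replicates were numbered within a group in the order of the samples. Whether the library preparation kept strand, the read length, the aligner and the read counter are not given in the sources used here.

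One table was used. Per its title line it lists genes that differed between the H3.3K27M and the other tumours. Per the submitters' processing notes, DESeq was used, with no version stated, and the genome builds mm9 and NCBIM37 are named. For each gene the table holds a signal that the authors deposited as normalized counts per tumour, their means per group, a ratio of the group means (fold change), its log2 value, a p-value and an adjusted p-value. The deposited group means equalled the means of the tumour columns, and the deposited log2 fold change equalled the log2 ratio of the H3.3K27M mean to the other mean. Columns were matched to tumours by the number that opens each title. There were 0 columns of per-tumour values without a matching sample.

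The adjusted p-values the authors deposited were checked against the Benjamini-Hochberg formula. With 16365 gene tests the formula returned every deposited value in the table, whose largest adjusted p was 0.0495. The table therefore holds each gene under an adjusted p of 0.05 among 16365 tests, and a gene that is not in it either stayed at or above that threshold or was not tested. Its absence says nothing more about its level.

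In each tumour's column, 100.0% of the values were whole multiples of one step, within 0.01 of a whole number, which is the form of read counts divided by a size factor. The implied size factors lay between 0.9169 and 1.0607. The reads behind the listed genes summed to between 215758 and 277881 per library. These sums cover the listed genes only, and the total depth of each library is unknown. The reads implied by the steps were used for counting limits of low genes and, in the closing observations, for a test of how reads were shared between histone H3 genes. For genes with 0 to 3 reads in a group the ratio of pooled reads, scaled by the size factors, is given with an exact 95% binomial interval, and a group with 0 reads was set to the limit of 3 reads that a count of 0 allows over the group. Intervals and limits cover counting error only. The listed genes hold too few low values to settle on their own that 1 step is 1 read. The read counts, intervals and the histone test rest on that reading, and for this reason too no count test was run.

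Means and SDs were computed from the normalized counts of the 3 tumours per group. Fold changes and adjusted p-values are those of the authors' deposited table. The design fixed before the data were examined called for a count test if the files held counts. As the values are normalized, limma 3.58.1 (R 4.3.3) was run in its place on log2(normalized count + 1), over the 223 listed genes, with Benjamini-Hochberg adjustment. The pseudocount shrinks the changes of low genes, while the use of mean log values can move a change either way against the deposited ratio of means. Because these genes had already been selected for a difference between the same tumours, limma here describes how far apart the libraries lie and is not independent evidence. On simulated counts with the real means, size factors and a dispersion of 0.02, with 200 of 2230 genes changed, the limma step recovered 97% of 2-fold and 100% of 4-fold changes, and 5.3% of its calls were unchanged genes. Listed genes such as Camk2a, at 654 ± 301 normalized counts in H3.3K27M tumours (SD, n = 3), vary more than this dispersion gives. Most simulated genes were also unchanged, so these rates do not carry over to the listed genes.

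Gene lists, 37 in number, were fixed before the data were examined. For lists with at least 3 members in the table, Fisher's exact test, two-sided, compared the split of members into higher and lower with that of the other listed genes, with Benjamini-Hochberg adjustment over lists. In a simulation on the 223 genes, this test called 3.9% of random lists of 8 genes and 99.2% of lists of 8 genes drawn to be mostly lower. As 81.6% of the listed genes were higher, the test has little power for short lists that are all higher, and the simulation did not cover these. The same test was run per chromosome with at least 5 listed genes. Sizes of change were compared between higher and lower genes, and the log2 fold change was correlated with the mean level, by two-sided permutation tests over genes with 100000 resamples. Genes are not independent replicates, so these p-values describe the table. Chromosomes come from GENCODE M21 on GRCm38, in which 220 of the 223 gene identifiers were found. As that is not the authors' build, no coordinates are given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

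Genes to name were set by a rule written before the data were examined. The rule took the genes of the study's design, the 10 largest rises and the 10 largest falls among genes at or above the median level of the table, the 5 smallest adjusted p-values in each direction, up to 4 members of each gene list, and up to 3 genes at 0 in one group. It gave 67 genes. Some genes that the rule or a count of calls would name are not reported here. Genes named outside it are marked as chosen after their values were seen. Alternatives set beforehand were adjusted p thresholds of 0.01 and 0.001, minimum absolute log2 fold changes of 1 and 2, leaving out genes under the lower quartile of levels, predicted and clone names, infinite fold changes or genes held by several lists, a pseudocount of 0.1, and leaving out each tumour in turn. Leaving out the neuron, synapse, astrocyte and myelin lists, and using the mean of the neuron list as a covariate, were chosen after seeing the data. That mean covers the neuron list members in the table only, which were themselves selected for a difference between the groups.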

Results

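Gene expression was measured by RNA sequencing in brainstem gliomas of C57BL/6 mice with a floxed p53 gene and the Nestin tv-a transgene, which places the receptor for an avian retrovirus on nestin-expressing progenitor cells so that such viruses can bring genes into them. All tumours had PDGF-B, a growth factor that drives glioma formation, and loss of p53. In 3 tumours the histone variant H3.3 with a lysine-to-methionine mutation (H3.3K27M), a hallmark of human diffuse midline glioma that inhibits the Polycomb methyltransferase PRC2, was present as well, and the other 3 tumours were without it. The titles of these other tumours read H3.3WT. Whether that marks an introduced wild-type H3.3 or only the mouse's own genes is not stated. The comparison asks which genes differ in expression between tumours with and without H3.3K27M. The deposited table holds normalized read counts of 223 genes in each of the 6 tumours. All titles of H3.3K27M tumours begin with 12 and all others with 11, so anything those numbers mark, which the labels do not state, cannot be separated from the mutation. The titles of H3.3K27M replicates 1 and 2 also share the number 623, where that of replicate 3 has 703; the design text calls all tumours independent, and what these numbers mark is not stated either.

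In H3.3K27M tumours, 17 of 71 neuron markers, 5 of 31 imprinted genes and 5 of 43 astrocyte markers were listed, all as higher. The 3 listed histone H3 genes were higher too. In the same tumours, 3 HoxA genes, the transcription factors Lhx2, Gata6 and Hlx and the cell cycle inhibitor locus Cdkn2a were lower. The authors' deposited table lists 223 genes at an adjusted p under 0.05, which is 1.36% of 16365 gene tests. Of these, 182 (81.6%) were higher and 41 were lower in H3.3K27M tumours. At least 2-fold differences were found for 133 of the higher and 13 of the lower genes. In 222 of the 223 genes the values of the 2 groups of 3 tumours did not overlap, a separation that chance gives in 10% of genes and that selection for significance favours. The exception was Gm4631, a predicted gene on chromosome 2, which was at 0 in all 3 H3.3K27M tumours and also at 0 in replicate 1 without the mutation, against 2494 and 1362 normalized counts in replicates 2 and 3. In limma its adjusted p lay between 0.0968 and 0.14 in 5 of the 6 fits that left out 1 tumour.

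Several developmental transcription factors were lower in H3.3K27M tumours. Hoxa4 (ENSMUSG00000000942), Hoxa5 (ENSMUSG00000038253) and Hoxa7 (ENSMUSG00000038236), homeobox genes of the HoxA cluster on chromosome 6 that specify position along the body axis in the hindbrain and spinal cord, were close to absent in H3.3K27M tumours. Hoxa4 had 2 reads over the 3 H3.3K27M libraries and 385 reads over the other 3, a 201.1-fold lower level with a counting interval of 55.3 to 1666.6. Hoxa5 had 2 against 467 reads, a 243.9-fold lower level with an interval of 67.2 to 2020.3. Hoxa7 had 0 against 77 reads and was at least 26.8-fold lower. The antisense transcript 2700086A05Rik, named Hoxaas3 in GENCODE M21, overlaps all 3 genes and had 0 against 64 reads, at least 22.3-fold lower. Since use of strand is not stated, its reads cannot be told apart from those of the genes it overlaps. The tumours without H3.3K27M varied widely among themselves, with 43.3, 118 and 241 normalized counts of Hoxa4. Without replicate 3 of that group, the ratios of the group means were 126 for Hoxa4 and 127 for Hoxa5, against 209 and 255 with it. In the authors' deposited table the adjusted p was 0.00728 for Hoxa4, 0.0319 for Hoxa5, 0.00193 for Hoxa7 and 0.00869 for the antisense transcript.

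Lhx2, a LIM homeobox factor of forebrain and eye development, was at 55.7 ± 34.6 normalized counts in H3.3K27M tumours and 303 ± 69.8 in the others (SD, n = 3 each). Gata6, a zinc finger factor of endoderm and heart development, was at 11.3 ± 11.9 against 113 ± 36.8, and the homeobox gene Hlx at 101 ± 13.2 against 274 ± 16.6. The authors' deposited table gives falls of 5.45-fold (adjusted p = 5.06e-07), 9.94-fold (adjusted p = 2.40e-05) and 2.72-fold (adjusted p = 5.44e-04), respectively. Without H3.3K27M replicate 3, which held 95.4 of Lhx2 and 25.1 of Gata6, the falls were 8.47-fold for Lhx2 and 25.2-fold for Gata6. Other regulators went the opposite way. Otx2, a homeobox factor of the forebrain and midbrain that is also expressed in choroid plexus, was at 206 ± 46.2 against 25.7 ± 24.5. Pbx3, a partner of Hox proteins, was at 653 ± 146 against 237 ± 40.8. Barhl1, a factor of cerebellar and midbrain neurons, was at 49.1 ± 18.9 against 5.32 ± 3.72. In the authors' deposited table Otx2 rose 8.01-fold (adjusted p = 3.31e-09), Pbx3 2.75-fold (adjusted p = 2.30e-04) and Barhl1 9.22-fold (adjusted p = 0.00921). A limma fit with the neuron mean as a covariate was chosen after seeing the data. In it the log2 change of Otx2 went from 4.16 to -1.61 (adjusted p = 0.698). That of Barhl1 went from 3.16 to -0.10 (adjusted p = 0.942), while that of Pbx3 was 1.90 (adjusted p = 0.176). The neuron means of the groups do not overlap, so the fit holds little information on the mutation. It cannot tell whether neurons account for these rises. One tumour without H3.3K27M held no Otx2 reads, the rise was 14.6-fold when replicate 2 of that group was left out, and in limma the adjusted p of Otx2 was 0.0734, 0.0567 or 0.0689 when H3.3K27M replicate 1, 2 or 3 was left out. Of the Hox list, which also holds Pbx partners, 1 member in the table rose and 3 fell (Fisher's exact p = 0.0204, adjusted p = 0.122 over 12 lists). Of the other developmental regulators, 2 rose and 3 fell (Fisher's exact p = 0.0443, adjusted p = 0.142). Neither split passed the adjusted threshold.

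**Figure D1:**
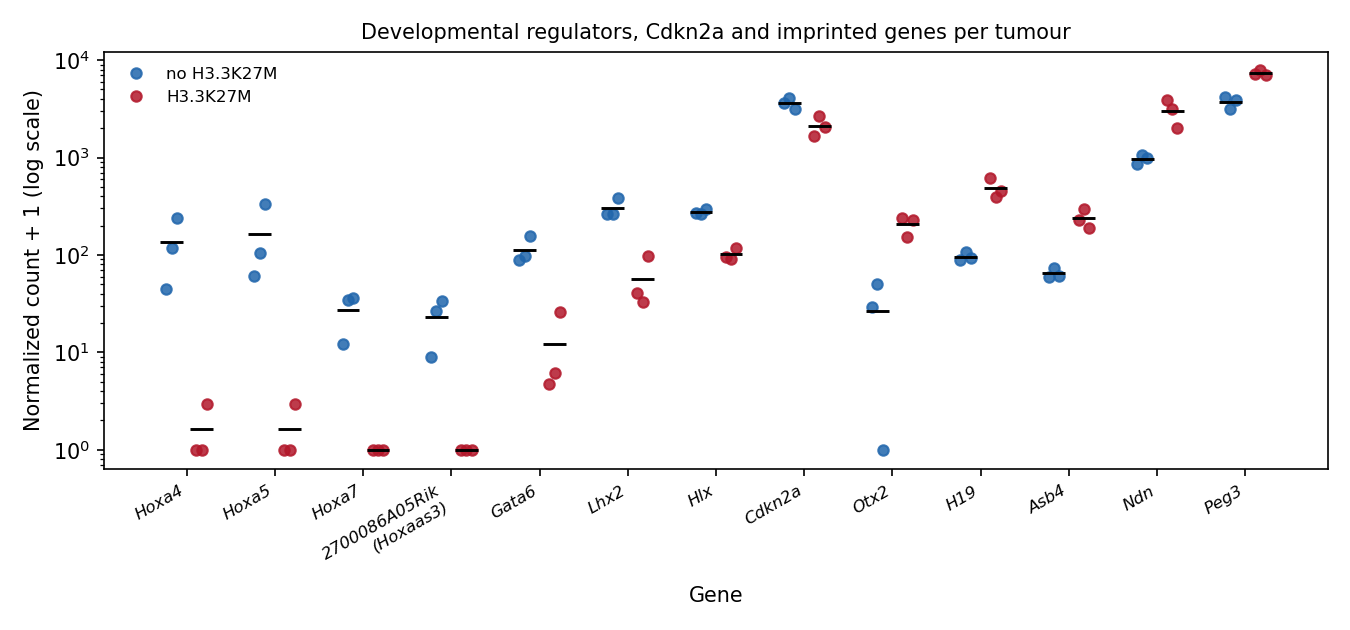
Normalized count + 1 (log scale) of 13 genes in each tumour without H3.3K27M (blue) and with H3.3K27M (red); each point is 1 tumour and each bar is the mean of 3 tumours. The HoxA genes lie at or close to 0 in all H3.3K27M tumours, and the imprinted genes H19, Asb4, Ndn and Peg3 lie higher in each H3.3K27M tumour than in any other.

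Of the 16 genes tied to the design, among them Pdgfb, Trp53, H3f3a, H3f3b, Pdgfra and Olig2, the table holds Cdkn2a alone. Cdkn2a (ENSMUSG00000044303, chromosome 4), which encodes the inhibitors p16 and p19Arf, was at 2125 ± 511 normalized counts in H3.3K27M tumours and 3636 ± 500 in the others (SD, n = 3 each). The authors' deposited table gives a 1.71-fold fall with adjusted p = 0.0176. The limma log2 change was -0.79, and its adjusted p was 0.0559 without H3.3K27M replicate 1 and 0.0549 without replicate 2 of the other group. As Pdgfb, Trp53 and the H3.3 genes are not in it, the genotypes in the labels could not be checked at those genes. No member of the p53 target, cell cycle, Polycomb component or chromatin modifier lists is in the table either. These lists are not complete. The table holds the cyclin gene Ccnd3, given in the closing observations, and the chromatin genes Cecr2 and Baz2b, all picked after their values were seen. In the authors' deposited table Cecr2 rose 4.72-fold (adjusted p = 3.88e-04) and Baz2b 1.63-fold (adjusted p = 0.0148).

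Among genes with a finite fold change, the steepest rises belonged to Hist1h3a, Hist1h3b and Hist1h3h, replication-dependent genes that encode the canonical histone H3. Hist1h3b was at 2270 ± 1028 normalized counts in H3.3K27M tumours and 2.68 ± 4.65 in the others (SD, n = 3 each), Hist1h3a at 2058 ± 880 against 3.76 ± 3.06, and Hist1h3h at 2213 ± 1006 against 4.44 ± 1.56. The authors' deposited table gives rises of 846-fold, 547-fold and 498-fold, with adjusted p-values of 3.21e-13, 1.21e-13 and 4.18e-12. These folds rest on few reads in the tumours without H3.3K27M. All 8 Hist1h3b reads there came from replicate 1, and against the other 2 libraries, with 0 reads, Hist1h3b was at least 1462-fold higher, with the limit of 3 reads set over both. Hist1h3a had 7, 1 and 3 reads, with a 969-fold rise without replicate 1, and Hist1h3h had 6, 3 and 4. These 3 genes carry an asterisk in the table that it does not explain. They share sequence, with 48%, 49% and 78% of the 50-base stretches of Hist1h3a, Hist1h3b and Hist1h3h found in the other 2, so reads could be split between them or come from another H3 sequence, and their levels are uncertain as levels of these genes.

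The neuron list had more members in the table than any other list, and all of these were higher in H3.3K27M tumours. Of 71 neuron markers, 17 are in the table, with 17 higher and 0 lower (Fisher's exact p = 0.0472, adjusted p = 0.142, against a table in which 81.6% of genes were higher). They include the kinase subunit Camk2a at 654 ± 301 against 81.7 ± 57.1 normalized counts, the chloride transporter Slc12a5 at 1313 ± 610 against 242 ± 109, the complexin Cplx1 at 1716 ± 633 against 386 ± 177 and the sodium channel subunit Scn4b at 322 ± 152 against 29.2 ± 16.1 (SD, n = 3 each). In the authors' deposited table these rises were 8.01-fold (adjusted p = 0.0125), 5.43-fold (adjusted p = 0.0449), 4.45-fold (adjusted p = 0.0127) and 11-fold (adjusted p = 0.00523). All 8 members of the synapse and ion channel list in the table were higher (Fisher's exact p = 0.357, adjusted p = 0.856). Among them, the calcium channel subunit Cacna2d1 rose 4.84-fold (adjusted p = 4.94e-05) and the synaptotagmin Syt7 2.19-fold (adjusted p = 0.00199) in the authors' deposited table. The mean log2 level of the 17 neuron members in the table was 9.91, 8.85 and 9.97 in H3.3K27M replicates 1, 2 and 3 and 7.74, 7.43 and 6.65 in the other tumours. These members were selected for a difference between the groups, so the gap between the means follows from that selection. The other members of the list have no value here.

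Of 43 astrocyte markers, 5 are in the table, with 5 higher and 0 lower (Fisher's exact p = 0.587, adjusted p = 0.881). Aqp4, the water channel of astrocyte endfeet, was at 695 ± 171 against 232 ± 68.9, and Aldh1l1, a folate enzyme used as an astrocyte marker, at 263 ± 62.1 against 88.1 ± 14.5 (SD, n = 3 each). The authors' deposited table gives 2.99-fold (adjusted p = 9.62e-04) and 2.98-fold (adjusted p = 1.94e-04). Of 37 myelin markers, 1 is in the table, Ermn, which rose 6.04-fold (adjusted p = 0.0207) in the authors' deposited table. The myelin gene Pllp, which the list does not hold and which was picked after its value was seen, fell 1.51-fold there (adjusted p = 0.0096). Without the members of the neuron, synapse, astrocyte and myelin lists, 28 genes that were all higher, the table held 154 higher and 41 lower genes.

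**Figure D2:**
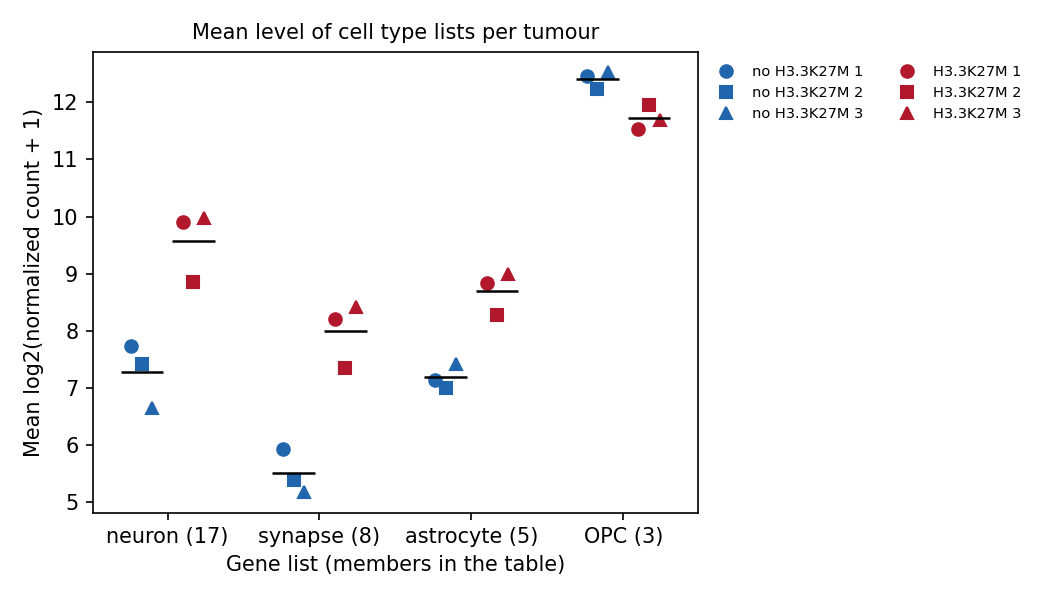
Mean log2(normalized count + 1) over the members in the table of the neuron, synapse, astrocyte and oligodendrocyte precursor (OPC) lists, per tumour without (blue) and with (red) H3.3K27M; symbols mark replicates 1 to 3 and bars the mean of 3 tumours. The neuron mean lies between 8.85 and 9.97 with H3.3K27M and between 6.65 and 7.74 without it, while the OPC mean runs the other way. All these members were selected for a difference between the groups, so the gaps follow from that selection.

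Of 36 markers of oligodendrocyte precursors 3 are in the table, and 0 were higher and 3 lower in the H3.3K27M tumours, in which neuron markers were higher (Fisher's exact p = 0.00585, adjusted p = 0.0702), which missed the adjusted threshold. Bcas1, expressed in cells entering oligodendrocyte differentiation, was at 9925 ± 1333 against 15092 ± 858 normalized counts. The Notch ligand Dll3 was at 563 ± 97.7 against 901 ± 111, and the calcium-binding protein Kcnip3 at 7122 ± 917 against 11906 ± 1847 (SD, n = 3 each). The authors' deposited table gives falls of 1.52-fold (adjusted p = 0.00304), 1.6-fold (adjusted p = 0.0295) and 1.67-fold (adjusted p = 0.00869). In limma the adjusted p of Bcas1 was 0.0555 and that of Dll3 0.0583 without H3.3K27M replicate 1, and that of Dll3 was 0.0532 without replicate 3 of the other group. Among further abundant genes that fell were the tetraspanin Cd9 at 5394 ± 819 against 9009 ± 420, the growth factor midkine (Mdk) at 753 ± 66.9 against 1265 ± 223, and the surface protein Cd24a at 840 ± 175 against 1522 ± 267 (SD, n = 3 each). Their falls in the authors' deposited table were 1.67-fold (adjusted p = 1.24e-04), 1.68-fold (adjusted p = 0.0128) and 1.81-fold (adjusted p = 0.0176).

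Imprinted genes, which are expressed from 1 parental allele, were all higher where the table holds them, with 5 of 31 list members in it (Fisher's exact p = 0.587, adjusted p = 0.881). The imprinted and neuron members in the table were selected for a difference between the same groups, so their joint rise shows no link between them. With the neuron mean as a covariate, 2 of 206 genes passed in limma, and that fit holds little information on the mutation. In it the log2 changes of H19, Peg3, Ndn and Asb4 were 1.87, 1.14, 1.99 and 2.41 (adjusted p = 0.136 to 0.238). Without the covariate they were 2.34, 1.00, 1.60 and 1.86. H19, a maternally expressed noncoding RNA, was at 491 ± 115 against 94.9 ± 9.35 normalized counts. Peg3, a paternally expressed zinc finger gene, was at 7390 ± 382 against 3717 ± 518, and Ndn, a paternally expressed gene of the Prader-Willi region, at 3026 ± 959 against 965 ± 109 (SD, n = 3 each). In the authors' deposited table they rose 5.17-fold (adjusted p = 2.14e-08), 1.99-fold (adjusted p = 1.12e-08) and 3.13-fold (adjusted p = 0.0116), and Asb4 rose 3.7-fold (adjusted p = 1.40e-05). The remaining list member, Usp29, named after its value was seen, rose 2.52-fold (adjusted p = 0.0195) there. H19, Peg3, Ndn and Usp29 lie on chromosome 7 and Asb4 on chromosome 6.

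Of the Notch, Wnt, Hedgehog and BMP list, 3 members rose and 1 fell (Fisher's exact p = 0.559, adjusted p = 0.881). The risen members were Smo and Ptch1, the signal transducer and the receptor of Hedgehog, and the receptor Notch2. Smo was at 571 ± 57.2 against 261 ± 23.8 and Ptch1 at 2141 ± 90.6 against 1373 ± 224 normalized counts (SD, n = 3 each), and the authors' deposited table gives 2.19-fold (adjusted p = 1.94e-04) and 1.56-fold (adjusted p = 0.00899). The member that fell was Dll3. All 3 receptor tyrosine kinase list members in the table (Erbb4, Igfbp5 and Epha3), all 4 of the axon guidance list, which include Slit2 and Flrt2, and all 3 of the mural and fibroblast list (Lum, Dcn and Lox) were higher (Fisher's exact p = 1 for each). In the authors' deposited table Lum and Dcn, proteoglycans of the extracellular matrix, rose 4.12-fold (adjusted p = 3.24e-04) and 3.65-fold (adjusted p = 0.0119). Lum rose 6.71-fold when replicate 3 of the tumours without H3.3K27M was left out. The chitinase-like macrophage gene Chi3l3 had 89 reads over the H3.3K27M libraries against 2, a 42.6-fold higher level with a counting interval of 11.5 to 357.2. Odz2, a teneurin that acts in neuronal connections, and the aminopeptidase gene Lnpep had the next smallest adjusted p-values after the histone genes in the authors' deposited table, with rises of 3.77-fold (adjusted p = 6.74e-12) and 3.35-fold (adjusted p = 2.09e-11).

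No list of the 12 with at least 3 members in the table had a split into higher and lower genes that passed the adjusted threshold, and 4 had an unadjusted Fisher's exact p under 0.05. Because 81.6% of the table was higher, a list of 3 to 8 members that are all higher could not pass this test. For 16 of the 37 lists no member is in the table, among them the interferon, antigen presentation, cytokine, lymphocyte, endothelial and brainstem nucleus lists. Counted as adjusted over the list alone, with members outside the table taken as far from significance, all 75 list memberships in the table passed as they do over all genes. The largest unadjusted p of the authors' test in the table was 0.000674, so the selection of the table all but fixed this outcome.

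The higher genes changed by more than the lower genes and were expressed at lower levels. The median absolute log2 fold change was 1.58 for 181 higher genes and 0.74 for 38 lower genes with finite values, a difference of 0.84 (permutation p = 8.00e-04). The median level was 286 normalized counts for higher and 1181 for lower genes. Across 219 genes the log2 fold change and the mean level had a Spearman correlation of -0.61 (permutation p = 1e-05, the smallest these permutations can give). The selection for significance truncates the table, and with a minimum absolute log2 fold change of 1 the difference in size was -0.09 (permutation p = 0.831). On none of 17 chromosomes did the split into higher and lower genes pass the adjusted threshold. Chromosome 15, with 4 higher and 4 lower genes, had the smallest p (Fisher's exact p = 0.0381, adjusted p = 0.648).

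**Figure D3:**
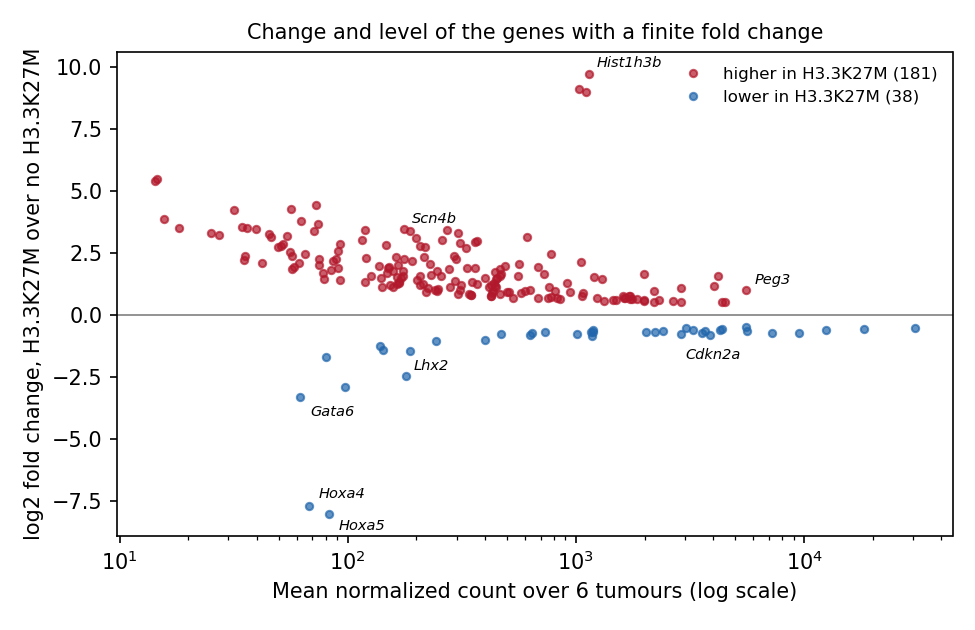
The log2 fold change (H3.3K27M over no H3.3K27M) of the 219 genes with a finite value against the mean normalized count over 6 tumours (log scale); each point is 1 gene. Among the 38 lower genes (blue), those with large falls such as Hoxa4, Hoxa5, Gata6 and Lhx2 lie at low levels, and the 181 higher genes (red) reach their largest changes at low levels, apart from the 3 histone H3 genes.

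In limma on the normalized counts of the 6 tumours, 223 of 223 genes passed an adjusted p of 0.05, 182 higher and 41 lower, which restates the selection of these genes. Without H3.3K27M replicate 1, 193 passed, 167 higher and 26 lower. With the mean of the neuron list as a covariate, an alternative chosen after seeing the data, 2 of 206 genes outside that list passed, among them Hist1h3h, and 43 had an unadjusted p under 0.05. The neuron means of the 2 groups do not overlap, so that fit holds little information on the mutation apart from the neuronal signal.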

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

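The counts depend on the threshold. Higher genes numbered 78 at an adjusted p under 0.01, 36 under 0.001 and 66 at an absolute log2 fold change of at least 2, and lower genes numbered 21, 5 and 8, with 13 at a log2 fold change of at least 1; each of these settings removes genes by construction. Higher genes numbered 133 at an absolute log2 fold change of at least 1. The remaining settings held 134 to 181 higher and 33 to 41 lower genes. The larger change of higher genes was 0.66 (permutation p = 0.286) under an adjusted p of 0.001, and it turned to -0.09 and -0.41 at minimum log2 fold changes of 1 and 2; the correlation with level was -0.17 at a minimum of 2. At minima of 1 and 2, 2 and 1 gene lists passed for direction (Hox genes in both, the other developmental regulators in the first), and at 2 so did 1 chromosome, number 6, where the HoxA genes lie. With genes held by several lists left out, the signalling list had 3 higher and 0 lower members, on the other side of the table's split, with adjusted p = 1. Limma called 220 of 223 genes with a pseudocount of 0.1 (of the named genes, Otx2 and Gm4631 were lost), 167 of 167 without genes under the lower quartile of levels and 193 to 220 with 1 tumour left out, lowest without H3.3K27M replicate 1 (167 higher, and 26 lower instead of 41), with 0 changes of sign. Among 67 named genes, 7 lost the call in at least 1 such fit: Cdkn2a, Otx2, Bcas1, Dll3, Gm4631, Rab3a (adjusted p = 0.0513 without H3.3K27M replicate 3 or without replicate 2 of the other group) and Chl1 (0.0559 without H3.3K27M replicate 1, 0.0563 without replicate 2 of the other group). With the neuron mean as covariate, chosen after seeing the data, 2 genes were called and the log2 change reversed for Dnajc6 (-0.32), Cd24a (0.05), Otx2 (-1.61), Barhl1 (-0.10), Dll3 (0.03), Nrn1 (-0.24) and Gm4631 (0.42); the cause was not tested. The planned count test was set for deposited counts and was not run on this table of normalized values. No paired analysis was possible because the labels give no numbers shared between the groups. Library depth is unknown, and for genes with 0 to 3 reads in a group counting error limits the fold change.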

Other observations

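Apart from the count of splits, the tests and values in this part were chosen after the results had been seen. The design fixed beforehand allowed a comparison with all measured genes only if the table also held genes that had not passed, which it does not. Set against all 16365 gene tests, and with every list member taken as tested, neuron markers were in the table more often than independent draws of genes give. They had 17 of 71 against 0.97 expected (exact hypergeometric p = 5.6e-17, adjusted p = 2.1e-15 over 37 lists). Imprinted genes followed with 5 of 31 against 0.42 (adjusted p = 0.0011), then astrocyte markers with 5 of 43 against 0.59 (adjusted p = 0.0035) and synapse genes with 8 of 143 against 1.95 (adjusted p = 0.0071). The Hox list, which also holds Pbx partners, had 4 of 44 against 0.60 (adjusted p = 0.022). Its members in the table are Pbx3, which rose, and 3 HoxA genes of one cluster, which fell and are overlapped by the same antisense transcript. Oligodendrocyte precursor markers, with 3 of 36, had an adjusted p of 0.08. Genes are not independent, and the neuron and synapse lists share members. The 17 neuron members varied together within groups (mean pairwise correlation 0.83), so these p-values overstate the evidence.

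Some genes not described so far were picked after their values were seen. The neuropeptide gene Cck was at 86 ± 30.6 against 12.8 ± 11.6 normalized counts, the proline transporter gene Slc6a7 of glutamatergic synapses at 107 ± 20.9 against 5.58 ± 5.87, and Bcl11a, a zinc finger factor of neurons and blood cells, at 162 ± 43.9 against 22.2 ± 7.91 (SD, n = 3 each). The progesterone receptor gene Pgr had 56 reads over the H3.3K27M libraries and 0 over the others, and was at least 17.9-fold higher. Among lower genes, Foxf1a, a forkhead factor of mesenchyme and a member of the developmental regulator list, was at 38.3 ± 7.25 against 123 ± 15, Runx3 at 78.8 ± 25.4 against 207 ± 61.9, and the D-type cyclin gene Ccnd3, which the cell cycle list does not hold, at 4626 ± 522 against 6518 ± 490.

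The 3 histone H3 genes rose together to nearly equal levels. Their reads kept one ratio across the 3 H3.3K27M libraries within counting noise (chi-square test of homogeneity, p = 0.441), as 1.59% of 10000 random trios of other higher genes did at p of at least 0.05. This is what reads of a single H3 sequence counted on genes that share sequence would give; 6 related H3 genes of the same cluster, with 21% to 79% of their 50-base stretches in the 3 genes, have no value here. Of the 50-base stretches of the 3 genes, 0 are found in the mouse H3.3 transcripts (H3f3a, H3f3b), where the longest shared stretch has 21 bases. Reads of an introduced gene with that sequence would match the H3.3 transcripts in full, and the 3 genes over at most 21 bases in a row. That argues against such a gene as the source, though read length and aligner are not given. An introduced H3 gene of another sequence, and a rise of the genes themselves with H3.3K27M, stay open and were not tested.

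Neuronal genes varied between tumours of the same group as well. The 17 neuron members had a mean pairwise correlation of 0.83 between their deviations from the group means, and 0 of 10000 random sets of other higher genes reached it (median 0.10), which is consistent with a different amount of neuronal tissue per specimen, and equally with a neuronal programme that varies between tumours. The 5 astrocyte members had a median correlation of 0.23 with the neuron mean (exact permutation p = 0.58, 36 relabellings within groups), too few values to say whether normal tissue brought astrocytes along. The 165 other higher genes had a median of 0.45 (exact permutation p = 0.028, the smallest these relabellings can give), so the within-group variation extends beyond the neuron list, and the 41 lower genes had a median of -0.39 (exact permutation p = 0.056). A difference between tumour series cannot be told apart from the mutation, because 0 of the numbers in the titles are shared by both groups, and an effect of H3.3K27M on neuronal genes stays open.

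The HoxA genes fell by more than most other lower genes, with Gm4631 as an exception, which was at 0 in 1 tumour without H3.3K27M too, so that its fall rests on 2 tumours. A lower share of tumour cells would lower genes that tumour cells alone express by about the same factor. The upper quartile of the falls of the other 37 lower genes was 1.99-fold, against at least 55.3-fold at the lower end of the interval for Hoxa4. This argues against a lower share only as far as these 37 genes are expressed by tumour cells alone, which was not tested. A larger amount of neurons in general in the tumours without H3.3K27M is argued against by the neuron members, of which 0 were higher there. These members do not mark position along the neural axis. Non-tumour cells from a level that expresses HoxA genes therefore stay open as the source of the HoxA reads. An origin of the tumours at another level of the neural axis could lower HoxA and raise Otx2 together, though Lhx2, a forebrain factor, fell, and it stays open: 0 Hox genes of the other clusters are among the lower genes, but those outside the table have no value here. A direct effect of H3.3K27M on the HoxA cluster was not tested, and group and title numbers coincide here too.

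Of the 10 splits of the 6 tumours into 3 and 3, 1, the real one, called 223 genes in limma, and the highest of the others called 0. With 10 splits the share cannot fall under 0.1, and the genes were selected on the real split.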
